A study of Saccharomyces cerevisiae with 67 samples.

How the data were processed

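The study mapped N6-methyladenosine (m6A), a methylated base of mRNA, in Saccharomyces cerevisiae strain SK1, a strain that sporulates efficiently. Per the labels' protocols, poly(A) RNA was chemically fragmented and immunoprecipitated with an anti-m6A antibody, and the eluted RNA went through a further immunoprecipitation. The labels describe 67 libraries, 34 from immunoprecipitated RNA and 33 from input RNA, in 29 conditions. The submitters' processing notes name Bowtie 0.12.7 and TopHat 1.4.1 without saying what each did. The peak caller, the threshold, the libraries that entered the list and the genome build are not given in the sources used here.

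The values analysed were 1 list, deposited with the series and tied to no library, in which each of 1308 rows was an interval of 1 base with a chromosome, a strand, a systematic gene name with a number attached, and a value. The authors deposited that value as a score whose scale, normalization and log base are not stated, and all scores lay between 2.01 and 6.87. It was treated as a number with an order within this list and nothing more. No column belonged to 1 library, so the depth of the libraries behind each site is unknown, there are no replicate values, and groups of libraries were not compared. The intervals below cover counting error over genes only.

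Systematic names were matched to a table of RefSeq genes of assembly R64 of the reference strain S288C. Of the 1308 sites, 1307 matched a gene, and 1306 of these named a protein-coding gene. The 1 unmatched name was YDR154C. Only 89 of the 1307 matched sites (6.81%) fell inside the R64 span of their gene. The positions are therefore not R64 positions, and they are given as the list gives them, counted from 1, with the build not named. The table was used for symbols, for gene order and for coding length, since 96.3% of its lengths were multiples of 3. Its lengths run from start to stop codon with introns included, so genes with introns, many ribosomal protein genes among them, have an overstated coding length. No sequence of the build in the list was used, so the planned tests of motif, neighbouring bases, predicted pairing and placement within the gene were not run. Whether each site is in a coding region or a UTR is likewise not analysed here.

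The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 8 genes with point mutants in the labels, 7 regulators (IME4, MUM2, SLZ1, IME1, RME1, NDT80 and PHO92), up to 4 members with a site from each list (most sites first, then alphabetical), the 10 genes with most sites and the 10 highest scores. A gene that this rule named is not reported here. All members of the 17 lists were found among the 6021 protein-coding genes. Each list's share of genes with at least 1 site was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 17 lists and a threshold of 0.05. Odds ratios had 0.5 added to each cell, with 95% Woolf intervals, and shares have exact Clopper-Pearson intervals. Alternatives fixed with them were a logistic model with log2 coding length (likelihood-ratio test), a Poisson model of site counts with a length offset, and sites at or above the median score only. After the data were seen, the square of log2 length was added to the logistic model, and that model was also run on the 5797 genes whose length is a multiple of 3, which leaves out most genes with an intron. Numbers of genes expected from length come from the model with the square over all genes. Scores of a list's sites were compared with all other sites by 100000 permutations of the median. The number of genes with several sites was compared with 10000 random scatterings of the sites over genes in proportion to coding length, because the planned weighting by sequence motifs needed a genome.

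A test added after seeing the data replaced placement within genes. For each pair of adjacent protein-coding genes in the R64 order that both held a site, the distance between the highest-scoring sites, in the list's own positions, was divided by the summed coding length. Convergent pairs have their stop codons next to each other, divergent pairs their start codons. Medians of orientations were compared by 100000 permutations, and the convergent median was compared with 100000 uniform placements along both coding regions with no gap between them. Medians have bootstrap 95% intervals. Gene order was assumed to be that of R64; the order of the sites followed it in all 224 pairs.

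The model with the square was tested on simulated data. With a true odds ratio of 3 for the 45 DNA replication genes, 89 of 100 runs over 6021 genes were called at an unadjusted p of 0.05, and with no effect 8 of 100 were. With a true odds ratio of 0.2 for the 137 cytoplasmic ribosomal protein genes, 96 of 97 runs were called. Runs in which no member had a site were left out. The values set were further from 1 than the estimates of this model, 2.39 and 0.42, and the calls were not adjusted over lists. Detection at the estimated values, or at an adjusted threshold, was not simulated. For the 62 convergent pairs, the uniform-placement test called 6 of 100 uniform runs and 100 of 100 runs with sites drawn towards the stop codon. In the latter the mean distance from the stop codon was 0.25 of the coding length, with no gap between genes. Their median distance was 0.233 of the summed coding length, below the observed 31.1%. A weaker pull towards the stop codon was not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.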

Results

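Libraries of m6A-immunoprecipitated and input poly(A) RNA were described for 29 conditions of SK1 yeast. They comprised wild-type cells (3 immunoprecipitated, 2 input libraries), a deletion of IME4, the m6A methyltransferase (3 of each), an IME4 catalytic mutant, wild-type and IME4-deleted cells labelled Veg, and a strain with an inducible MIS complex with and without induction. An early meiosis time course had 7 time points from 0 min to 3 hr, and a release time course had 5 time points. A further set comprised 8 strains with a point mutation named for a gene, an IME2 deletion as a negative control and 2 replicates of an ash1 deletion as a positive control. The values analysed were a list of 1308 m6A sites given for the series, without the libraries it was called from. It holds no value per library, so the contrasts between these conditions are not analysed here, and each comparison below is between genes or between sites of that list.

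The list placed m6A sites in 1179 of 6021 protein-coding genes, a share of 19.6% (exact 95% interval 18.6 to 20.6%). Sites were split evenly between strands, with 654 on each, and lay on all 16 nuclear chromosomes, with 14 to 172 sites per chromosome. Of 1181 systematic names, 1063 had 1 site, 109 had 2 and 9 had 3. The median score was 3.26 (interquartile range 2.76 to 3.90). The score is the authors' own, on an unstated scale.

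The highest score, 6.87, belonged to a site in TRE1 (YPL176C; chromosome 16, position 225521, reverse strand), which encodes a transferrin receptor-like protein. It was followed by SEC28 at 6.47 (YIL076W; chromosome 9, position 220069), a subunit of the COPI vesicle coat, FAS1 at 6.34 (YKL182W; chromosome 11, position 107890), a subunit of fatty acid synthetase, and VAC8 at 6.27 (YEL013W; chromosome 5, position 135299), a vacuolar membrane protein. Next came CSR2 at 6.09, ATM1, a mitochondrial ABC transporter, at 6.08, GDE1, a glycerophosphodiesterase, at 6.07, IMO32 at 6.05, the splicing factor gene NAM8 at 6.05 and STT4, a phosphatidylinositol kinase, at 6.04. These scores have no replicate error, so their order within the list is descriptive.

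The point mutant strains ask about single sites in named genes, and all 8 of those genes had exactly 1 listed site. NAM8 (YHR086W; chromosome 8, position 278878, forward strand) scored 6.05, rank 9 of 1308. MEI5 (YPL121C; chromosome 16, position 330846, reverse strand), a meiotic recombination gene, scored 4.68 at rank 102, and YLR149C, named GID11 in the gene table (chromosome 12, position 436936, reverse strand), scored 4.33 at rank 184. YSP3 (YOR003W; chromosome 15, position 333684, forward strand) scored 3.93. IME2, a kinase that drives meiotic entry (YJL106W; chromosome 10, position 232120, forward strand), scored 3.82. ZIP1, a component of the synaptonemal complex (YDR285W; chromosome 4, position 1032298, forward strand), scored 3.57. MUS81, a subunit of a structure-selective endonuclease (YDR386W; chromosome 4, position 1239083, forward strand), scored 3.48, and YNL195C (chromosome 14, position 290244, reverse strand) scored 3.31. All 8 sites scored above the median of all sites. The median of the 8 scores was 3.87 against 3.25 for the other sites, a difference that did not pass a two-sided permutation test (adjusted p = 0.74 over 16 comparisons, unadjusted p = 0.072). The study chose these genes for mutation, on grounds not given in the sources used here, so their presence in the list (adjusted p = 1.8e-05, Fisher's exact test) is not taken as independent evidence.

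Genes of the methylation machinery had no listed site. IME4, MUM2 and SLZ1, which form the MIS complex, KAR4, VIR1 and DYN2 were absent from the list, as was PHO92, which encodes an m6A reader. This share of 0 of 7 has an exact 95% interval reaching 41.0%, so these genes could not be told from the rest (adjusted p = 0.51, Fisher's exact test). IME1, the master activator of meiotic entry, RME1, its repressor, and NDT80, the activator of middle meiosis, had no listed site either.

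Genes of meiosis carried sites at shares that did not differ detectably from other genes. Among recombination and double-strand break genes, 12 of 37 had a site (32.4%, exact 95% interval 18.0 to 49.8%). They included RAD54 and RAD57, both strand-exchange factors, and the checkpoint kinase gene TEL1, each with 2 sites, and the exonuclease gene EXO1 with 1. The odds ratio was 2.02 (95% interval 1.03 to 3.99), with an adjusted p of 0.20 by Fisher's exact test. Chromosome axis, synapsis and meiosis I genes had a site in 7 of 24 (29.2%), with 2 sites in the cohesin loader gene SCC2 and 1 each in HOP1, PDS5 and SMC3 (odds ratio 1.76, adjusted p = 0.51, Fisher's exact test). Meiotic entry regulators had a site in 6 of 21 (28.6%). These were led by the kinase gene SNF1 with 2 sites, followed by IME2, RIM101 and STU1, the last of which is known as a spindle microtubule-binding protein gene (odds ratio 1.73, adjusted p = 0.51, Fisher's exact test). Of the 6 meiotic splicing genes, NAM8, HFM1 and SPO22 had a site (adjusted p = 0.23, Fisher's exact test). MUS81, MEI5, ZIP1, IME2 and NAM8 are members of these lists that the study also chose for mutation.

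Genes used later in sporulation did not differ detectably from other genes either. Middle sporulation genes had a site in 7 of 41 (17.1%, exact 95% interval 7.15 to 32.1%), among them ADY3 and ADY4, of the meiotic spindle pole body, the polo kinase gene CDC5 and SPO1 (odds ratio 0.89, adjusted p = 0.84, Fisher's exact test). Of 14 late spore wall genes, CHS3, a chitin synthase gene, was the 1 with a site (odds ratio 0.46, adjusted p = 0.51, Fisher's exact test).

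DNA replication genes carried sites more often than other genes. Of 45 members, 19 had a site (42.2%, exact 95% interval 27.7 to 57.8%), an odds ratio of 3.05 (95% interval 1.70 to 5.50; adjusted p = 0.0024, Fisher's exact test). CDC9, the DNA ligase gene, scored 5.06, CDC45, of the replicative helicase, 4.19, DPB11, of replication initiation, 3.36, and DBF4, the regulatory subunit of the Cdc7 kinase, 2.89. The members were long, with a median coding length of 1716 bases, and length alone predicted 11.3 members with a site. With length in a logistic model (n = 6021 genes) the odds ratio was 2.48 (95% interval 1.32 to 4.65; adjusted p = 0.064, likelihood-ratio test), so the call was lost over the 15 lists that this model could fit.

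Ribosomal protein genes carried sites less often than other genes before coding length was considered. Of 137 cytoplasmic members 6 had a site (4.38%, exact 95% interval 1.62 to 9.29%; odds ratio 0.20, 95% interval 0.09 to 0.44; adjusted p = 5.2e-06, Fisher's exact test). RPL19B had a site with a score of 4.02, RPL25 a site with 3.68, RPL15B a site with 3.41 and RPL20B a site with 3.25. RPL19B, RPL15B and RPL20B each have a near-identical copy, so which copy the reads came from is uncertain. Of 67 mitochondrial members, MRP1, MRP20 and RSM23 had a site (4.48%; odds ratio 0.22, 95% interval 0.08 to 0.65; adjusted p = 0.0024, Fisher's exact test). Both groups are short, with median coding lengths of 771 and 699 bases. With length in the model (n = 6021 genes), the odds ratios were 0.40 (95% interval 0.17 to 0.91; adjusted p = 0.064) and 0.45 (95% interval 0.14 to 1.45; adjusted p = 0.50), and neither call held. Lengths include introns, and among the 80 cytoplasmic members whose length is a multiple of 3, where fewer have an intron, 5 had a site and the odds ratio in the model with the square was 0.72 (95% interval 0.29 to 1.83).

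The other lists did not differ detectably by Fisher's exact test. Proteasome genes had a site in 11 of 34 (32.4%), including PRE5, PRE6, PRE7 and PRE9 (odds ratio 2.02, 95% interval 0.99 to 4.10; adjusted p = 0.22, Fisher's exact test). Their short coding lengths predicted 5.33 members, and the length-adjusted odds ratio was 2.82 (95% interval 1.34 to 5.94; adjusted p = 0.064, n = 6021 genes). Kinases and cell cycle control genes had a site in 12 of 40 (30.0%), with 2 sites each in SCH9, SNF1, TOR1 and YAK1, all nutrient-signalling kinase genes. Autophagy genes had a site in 9 of 37 (24.3%), with 2 sites in ATG9 and 1 each in ATG1, ATG11 and ATG13. In TCA and glyoxylate cycle genes the count was 6 of 25 (24.0%), including SDH1 with 2 sites, and ACS1 and CIT1. In glycolysis and gluconeogenesis genes it was 5 of 22 (22.7%), including the pyruvate carboxylase genes PYC1 and PYC2 with 2 sites each, and HXK1 and HXK2. In translation initiation and tRNA synthetase genes it was 9 of 42 (21.4%), including ALA1, CDC60, DED1 and GCD6. Adjusted p-values for these last 5 lists ran from 0.23 to 0.84 by Fisher's exact test.

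**Figure D1:**
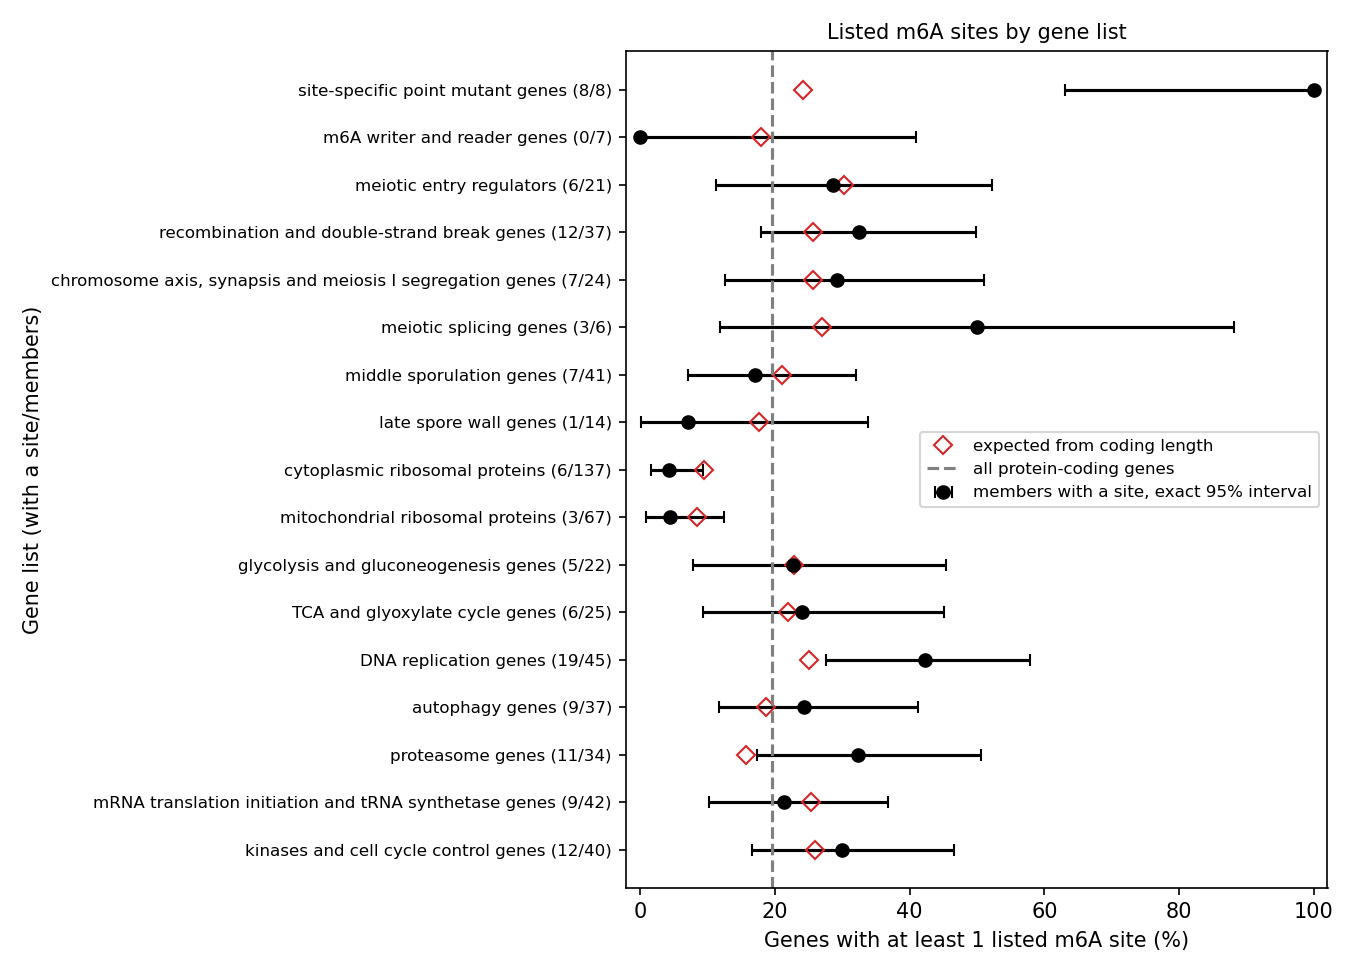
Share of genes with at least 1 listed m6A site (x axis, percent) for the 17 gene lists (y axis); points are observed shares with exact 95% intervals, open diamonds the share expected from coding length, and the dashed line all protein-coding genes at 19.6%. DNA replication genes (42.2%) lie above the line and cytoplasmic (4.38%) and mitochondrial (4.48%) ribosomal protein genes below it; the point mutant genes were chosen by the study.

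Longer genes carried sites more often. Among the 1205 shortest genes (the lowest of 5 equal groups by coding length, median 393 bases), 41 had a site (3.40%, exact 95% interval 2.45 to 4.59%). The share was 11.0% at a median of 816 bases, 17.0% at 1203, 24.4% at 1713, and 42.0% (39.2 to 44.9%) among the 1204 longest genes at 2856 bases. The intervals of adjacent groups did not overlap. Of the 118 genes with several sites, 97 were in the longest group.

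**Figure D2:**
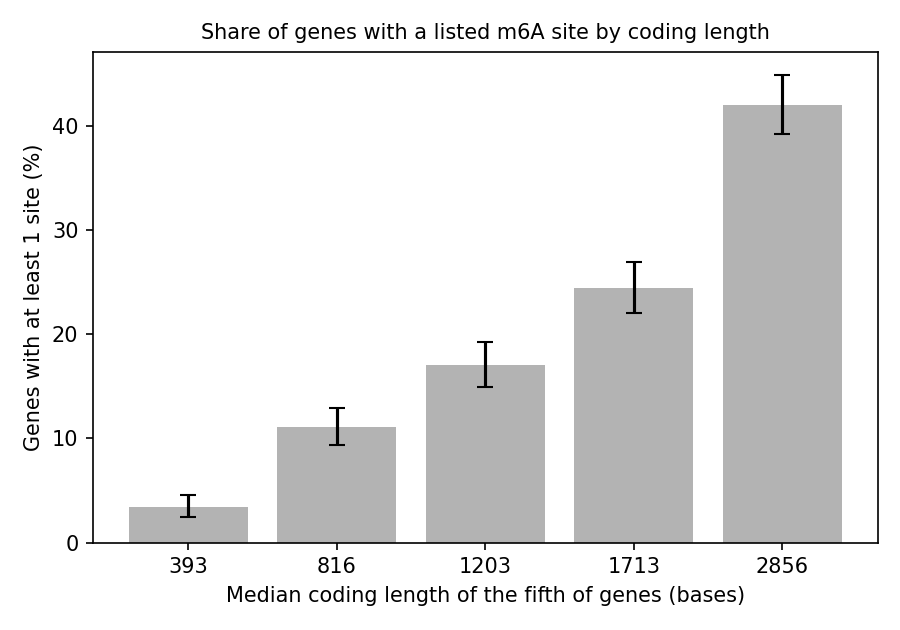
Percentage of protein-coding genes with at least 1 listed site (y axis) in 5 equal groups by coding length (x axis, median length in bases); bars are shares and error bars exact 95% intervals. The share goes from 3.40% in the shortest group to 42.0% in the longest.

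The 9 genes with 3 sites were PBY1, SIR4, PAN2, MDS3, XRN1, CYR1, FAS1, APE2 and NCR1. PAN2 encodes a poly(A)-specific nuclease and XRN1 the main cytoplasmic exoribonuclease of mRNA decay, SIR4 a silencing factor and CYR1 adenylate cyclase. Their highest scores were 4.27 for PAN2, 3.61 for XRN1, 5.76 for SIR4 and 4.21 for CYR1. Next was PTA1, an mRNA cleavage and polyadenylation factor gene, the first by systematic name among genes with 2 sites. Genes with at least 2 sites numbered 118, fewer than the 165.7 on average when sites were scattered in proportion to coding length (95% of scatterings 147 to 185; two-sided permutation p = 0.0002, the smallest these draws can give). With every gene given the same weight the average was 122.7 and the difference was not significant (permutation p = 0.65). The closest listed sites in a gene were 184 bases apart, and the median span was 1035.5 bases, or 35.0% of the coding length. The scatterings allowed sites of a gene at any spacing. Whether the peak calling joined nearby sites is not given, so a lower count from that source cannot be told apart. Scores of sites in genes with several sites (median 3.34) did not differ detectably from those in genes with 1 site (3.24; permutation test, adjusted p = 0.74), nor did the sites of any list with at least 3 sites differ from other sites (16 comparisons, lowest unadjusted permutation p = 0.072).

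Where sites lie along genes was addressed through neighbouring genes that both held a site, a comparison chosen after the data were seen. Sites of convergent neighbours, whose stop codons face each other, lay close together, and sites of divergent neighbours lay far apart. The median distance was 1080 bases in 62 convergent pairs (bootstrap 95% interval 842 to 1518.5), 2538.5 bases in 106 tandem pairs (2223.5 to 2747.5) and 3497 bases in 56 divergent pairs (2899 to 3931.5). As a share of the summed coding length the medians were 31.1% (27.9 to 36.5%), 62.2% (55.4 to 68.5%) and 84.3% (75.6 to 88.1%). Each pair of orientations differed in this distance (two-sided permutation tests, adjusted p = 1e-05, the smallest these draws can give). Distances include the gap between the genes, which lengthens them unequally, since divergent genes have both promoters between them and convergent genes none, so these differences do not by themselves show where in the genes the sites lie. The comparison of convergent pairs with uniform placement does not depend on the other orientations. In uniform placement with no gap, the medians of convergent pairs averaged 50.0%, and the lowest of 100000 was 34.3%, above the observed 31.1% (one-sided permutation p = 1e-05). The distance was under 50% of the summed length in 47 of 62 convergent pairs and in 5 of 56 divergent pairs. Some genes (12) were in both a convergent and a divergent pair, and further genes were shared with or among tandem pairs. The pairs are therefore not fully independent, although the permutation tests treated them so.

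**Figure D3:**
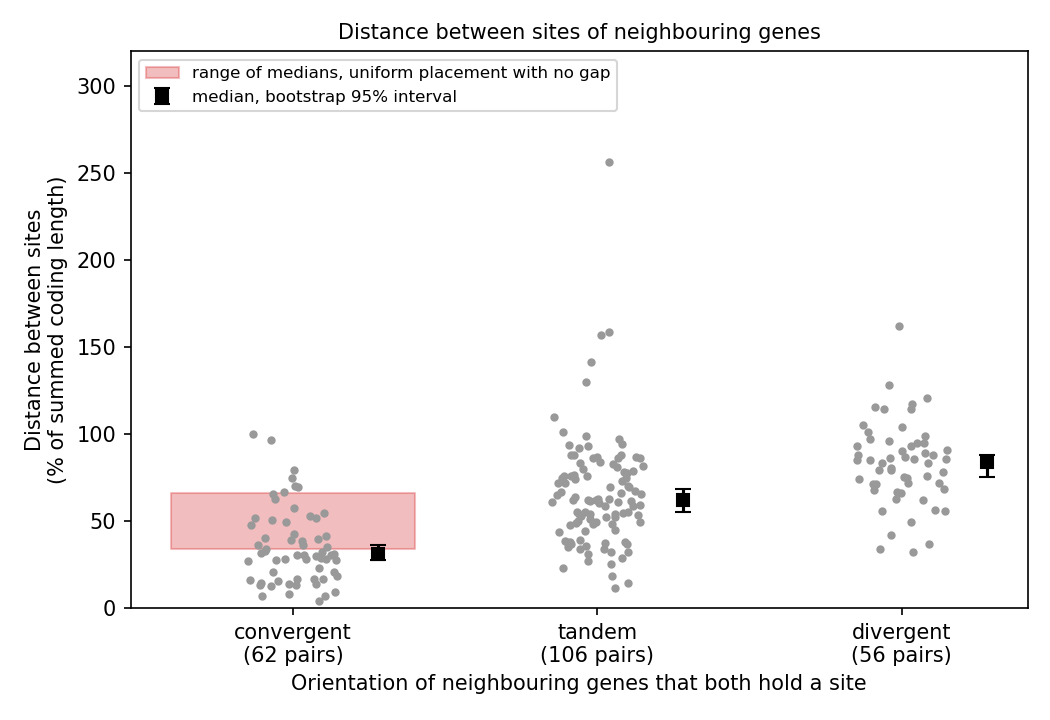
Distance between the highest-scoring sites of neighbouring genes, as a percentage of their summed coding length (y axis), for convergent, tandem and divergent pairs (x axis); grey points are pairs, squares are medians with bootstrap 95% intervals, and the shaded band is the range of medians under uniform placement with no gap. The convergent median of 31.1% lies below the band, and the divergent median is 84.3%.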

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

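The models with squared length, the runs on lengths that are multiples of 3, on nuclear genes, without the mutated genes and without the 20 outermost genes of each chromosome end, the equal weights, the highest site per gene, the lists gathered by prefix and the spacing of neighbours were chosen after seeing the data. No paired analysis was possible because the list has no value per library, so no replicate was left out either. Scores at or above the median left 654 sites and 618 genes. Of 17 lists, 4 passed by Fisher's exact test, the study's own mutated genes among them. Of the 15 lists that could be fitted, 0 passed in the logistic model with length (3 at an unadjusted p under 0.05), 0 with its square (3) and 0 on lengths that are multiples of 3 (2). In the Poisson model 1 passed, the mutated genes. In that order of models, ratios were 0.40, 0.42, 0.72 and 0.40 for cytoplasmic ribosomal proteins, with adjusted p-values (n = 6021 genes, 5797 in the third) from 0.064 to 0.74. They were 0.45, 0.49, 0.49 and 0.44 for mitochondrial ones (0.32 to 0.71), and 2.48, 2.39, 2.31 and 1.58 for DNA replication genes (0.064 to 0.26). All lay nearer 1 than by Fisher's exact test; the models differ in their terms, genes and kind of ratio, and the cause of each move was not tested. At scores at or above the median, mitochondrial ribosomal proteins missed the threshold (0.19, adjusted p = 0.055, Fisher's exact test), where fewer sites were tested. Genes with several sites were 0.71 of the length-weighted expectation and 0.96 with equal weights (permutation p = 0.65). No score comparison passed, except 1 with the highest site per gene, for genes with several sites, whose highest value is larger by construction. Leaving out prefix-sharing genes of other function moved no call of the secretory or ribosome biogenesis lists. The convergent median stayed between 27.5% and 32.2% with other choices of site or each chromosome left out. Not run, without a genome of the list's build: gene overlap and UTR settings, motif, base and folding tests, and backgrounds or weights by motif; a background without dubious genes was not run either. Library depth is unknown.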

Other observations

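The length-adjusted tests of ribosomal protein and DNA replication genes were fixed before the data were examined, without the square of length; the tests of ribosome biogenesis, secretory, nuclear pore and unnamed genes, of symbol stems, of copy number, of identifiers and of convergent neighbours were chosen only after related values had been seen. So were the bounds that the length-adjusted odds ratios were held against. Of 103 ribosome biogenesis genes, 5 had a site (4.85%), where coding length predicted 24.0. The list was gathered by symbol prefix after a look at groups of symbols, and not every gene of each prefix was taken. The length-adjusted odds ratio was 0.15 (95% interval 0.06 to 0.38; adjusted p = 2.4e-07 over 5 gene sets, likelihood-ratio test, n = 6021 genes). The 5 were UTP20 and RRP5 with 2 sites each, and NSA1, DBP7 and REA1 with 1. Only some of the DBP genes (2 of 9 had a site) and of the MAK genes (1 of 8) were in the list. DBP7 was the only gene with a site taken from these prefixes, so others with a site were left out. A list with all genes of these prefixes was not tested. The prefixes also brought in IMP1, IMP2 and IMP21, which have other functions and no site, and without them the odds ratio was 0.15 (95% interval 0.06 to 0.38). The pattern was noticed in genes named UTP and NOP. Among the other 68 members 4 had a site against 15.3 expected from length (odds ratio 0.20, 95% interval 0.07 to 0.55, adjusted p = 0.00017, likelihood-ratio test, n = 6021 genes). Within this list the low count thus did not rest on the UTP and NOP genes alone. The other members are no independent test, since counts by symbol stem had been seen first. They include the RRP genes, of which 1 of 18 had a site against 3.40 expected. The adjustment does not cover the choice of these sets after a look at the data. Transcript abundance is not in the list and was not tested.

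Genes without a standard symbol also had fewer sites than length predicts, 55 of 746 against 94.6 (length-adjusted odds ratio 0.46, 95% interval 0.34 to 0.63, adjusted p = 2.4e-07, likelihood-ratio test, n = 6021 genes). The adjustment does not cover the choice of this set after a look at the data. Neither transcript abundance nor a background without dubious genes was tested, so a lower count from these sources cannot be told apart. Secretory pathway genes had a site in 40 of 136 against 31.3 expected, in a list gathered by symbol prefix. The length-adjusted odds ratio of 1.47 (95% interval 0.99 to 2.20; adjusted p = 0.079, n = 6021 genes) did not pass, nor did that of 1.51 (1.00 to 2.27; adjusted p = 0.065) without RET1, VPS71, VPS72, VPS75, SED1 and ERV1, which have other functions. Nuclear pore genes had a site in 14 of 31 against 10.3 expected, with a length-adjusted odds ratio of 1.71 (95% interval 0.82 to 3.58; adjusted p = 0.16, n = 6021 genes). Of 90 groups of at least 8 genes sharing a symbol stem, 0 passed the threshold and 8 had an unadjusted exact p under 0.05; the SEC genes (17 of 36, 9.57 expected) had the lowest p, 0.0082 (adjusted p = 0.34).

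Sites of convergent neighbours lay at a median of 31.1% of the summed coding length. Uniform placement along both coding regions is argued against, since the lowest simulated median was 34.3% and gaps between genes would raise it. This is consistent with sites lying towards the 3' ends of genes, a hypothesis tested on the data it came from. Uneven read coverage after poly(A) selection stays open: coverage is not in the list, and the median span of 1035.5 bases between sites of 1 gene does not decide it.

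The low share of cytoplasmic ribosomal protein genes cannot be told apart from an effect of length. The odds ratio moved from 0.20 (95% interval 0.09 to 0.44) to 0.42 (0.18 to 0.96) with length and its square in the model, with an upper bound of 0.964. Introns overstate the length of many of these genes, and on lengths that are multiples of 3 the odds ratio was 0.72 (0.29 to 1.83), so the difference was no longer detectable. That run left members out and did not correct their lengths, going from 6 of 137 with a site to 5 of 80. It therefore does not show what corrected lengths would give. Reads shared between copies stay open too: of 19 single-copy members 1 had a site against 1.43 expected (exact one-sided p = 0.57), and of 118 duplicated members 5 against 11.6 (exact one-sided p = 0.020), expectations that the introns raise. With so few expected, the single-copy test could not have passed even with no site in these members, so it cannot decide the question. No biological explanation was tested, since the list has no value per condition.

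For DNA replication genes the odds ratio moved from 3.05 (95% interval 1.70 to 5.50) to 2.39 (1.27 to 4.49) with length and its square in the model, and 2.31 (1.23 to 4.36) on lengths that are multiples of 3. The lower bound of 1.27 lies above 1, but it is not adjusted over lists, and the square was added after the data were seen. The call over all lists was lost (unadjusted p = 0.0082, adjusted p = 0.095, likelihood-ratio test, n = 6021 genes). In the planned Poisson model the rate ratio was 1.58 (95% interval 1.003 to 2.48), and the call was lost there too. Long coding regions as the whole cause therefore stay open. The ratio, the test and the number of lists changed together, so what ended the call was not separated. Transcript abundance in the libraries used for calling may differ for these genes and stays open, as the list does not give it.

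The number attached to each site's gene name, which ran from 81 to 15642, went with the score (across sites, which are not independent replicates: Spearman's rho = -0.42, Pearson's r = -0.43). The 908 sites numbered below 8000, a bound chosen after seeing the data, had a median score of 3.55 (interquartile range 3.06 to 4.16), and the 400 others 2.75 (2.46 to 3.10). What the number stands for is not given in the sources used here.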
